A study of Homo sapiens with 8 samples.

How the data were processed

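RNA was extracted from DND41 cells after 72 h of doxycycline and sequenced from strand-specific libraries, per the labels' protocols. The 8 libraries comprised 3 with the SIRT1 construct sh1, 3 with the SIRT1 construct sh3 and 2 with the control shRNA, grouped by their titles. What the numbers in sh1 and sh3 stand for is not stated in the labels, and a control with the letter B was not analysed here. The sh3 library with the letter C is placed in the SIRT1 arm by its title and genotype and named as a control in its description, and it was analysed with sh3.

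The deposited values are a signal in normalized counts per gene symbol, and the submitters' processing notes list kallisto 0.44.0, DESeq and the build hg38. The transcript annotation, the summary of transcripts to genes and any filter are not given in the sources used here. The values are not whole numbers, and 29.9% to 45.2% of low values per library lay within 0.02 of a whole multiple of the step at which that library's lowest values pile up. Whole reads could not be recovered from the values, the cause of this was not tested, and a test for counts was therefore not used. That step was near 1 normalized count, so that genes near the floor rest on few steps. The 10 most abundant genes took 4.54% to 4.96% of each library, mitochondrially encoded genes took 2.71% to 3.07%, and between 326 and 544 rows were at 0.

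Of 18133 rows, 18031 matched a symbol of GENCODE release 29 on GRCh38, the assembly that hg38 denotes, and 15514 of these were protein coding and 2401 pseudogenes. Coordinates are given on that build and annotation. Sharing of reads between paralogs or with pseudogenes cannot be excluded from the values, so that RASA4B, UTP14C, SOD1P3, FCGR2A, FTH1, H3F3A, H3F3B and the ribosomal protein genes are uncertain, since reads could be split between near-identical copies. Several named genes overlap another coding gene, among them SHC4 with EID1, EMP3 with CCDC114, CASKIN1 with TRAF7, KAT7 with FAM117A and FTH1 with BEST1, and whether the authors' counting used the strand is not given in the sources used here.

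The values were analysed as log2(value + 1) for the 13885 genes with a mean of at least 10 over the 8 libraries, which removed 4248 rows. Fold changes are on that scale, which understates the change of low genes. A single limma 3.58.1 model in R 4.3.3 held 3 group means, since the control arm has 2 libraries and the groups then share an estimate of the spread, with 5 residual degrees of freedom and an empirical Bayes variance prior that followed the mean (trend). The contrasts were the mean of the SIRT1 constructs against control, each construct against control, and sh1 against sh3. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes were called at an adjusted p under 0.05.

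Before the data were examined, 32 gene lists were fixed from textbook knowledge, among them targets of NOTCH1, MYC, FOXO and NF-kB, the interferon, hypoxia, ATF4, ER unfolded protein, heat shock and NRF2 responses, DNA replication, mitosis, nuclear and mitochondrial genes of oxidative phosphorylation, the TCA cycle with fatty acid oxidation, glycolysis, cholesterol synthesis, lysosome and autophagy, ribosomal proteins, sirtuins and NAD metabolism, histone acetylation enzymes, the BCL2 family, T cell identity, T-ALL transcription factors, early activation, histones, and markers of myeloid, B, NK, erythroid and adherent cells. The lists hold 835 different symbols, some of them in several lists. Of these symbols 773 were found, 28 of them under an older symbol. The 31 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. At an estimated correlation camera uses the 5 residual degrees of freedom of the model, and at the preset one a far larger number set by the genes tested. Its p-values at an estimated correlation are therefore larger even where genes of a list do not vary together.

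The genes named in the text were chosen by a rule written before the data were examined. The rule took SIRT1, NOTCH1, MYC, HES1, DTX1 and KAT7, then the 10 largest rises and 10 largest falls of the main contrast among genes past the threshold with a mean of at least 50 and every knockdown library beyond both controls, and the 5 largest rises and falls of each other contrast by the same criteria. Some genes that the rule took and a list are not reported here, and counts include them. It passed over clone-based names, ribosomal protein pseudogenes, Y-linked genes and XIST. It added the 3 members of each list with the smallest p among those past the threshold, and the most abundant member of each list of other cell types.

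The procedure was tested on simulated data for the knockdown against control comparison over 13885 genes, of which 200 were changed. It recovered 81% of changes of 0.5 and 98% of changes of 1 on the log2 scale, with 14 false calls among 193. The changes were placed in genes with a mean of at least 50, and the noise was drawn independently for each gene from the fitted spread. The false calls therefore do not cover genes that vary together. The alternatives were other pseudocounts, filters and scalings, other variance priors, a replicate block, library weights, fits on fewer groups and the omission of each library. Removal of the trend with transcript length and GC content and a fit on the letters A and C were added after the data were seen. Heptamers in annotated 3' untranslated regions were scored against the fold changes with adjustment for region length, GC content and mean level. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.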

Results

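Messenger RNA levels were compared in DND41 cells, an established human T-cell acute lymphoblastic leukemia (T-ALL) line that carries an activating NOTCH1 mutation, after 72 h of doxycycline. Doxycycline switched on a short hairpin RNA (shRNA) against SIRT1, a nuclear NAD-dependent protein deacetylase, or a control shRNA. The SIRT1 arm used 2 constructs, here called sh1 and sh3 after their labels, with 3 libraries each (A, B and C), and the control arm had 2 libraries (A and C). The library sh3 C carries a contradiction in its labels, since its title and genotype place it in the SIRT1 arm and its description names the control shRNA. It was kept with sh3, and its values correlated with those of the other sh3 libraries at a Spearman coefficient of at least 0.9955 across genes, against at most 0.9925 with the controls. Normalized counts summed to between 33087820 and 34072666 per library. The lowest values piled up at a step of 0.884 to 1.15 normalized counts, depending on the library. Of 18133 rows, 13885 had a mean of at least 10 and were tested. The cells were plated in triplicate, and nothing in the labels says that the replicates came from separate infections, so that p-values measure the spread between these cultures, which may be technical.

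SIRT1 messenger RNA was lower in all 6 libraries with a SIRT1 hairpin than in both controls. SIRT1 (chromosome 10, 67884669 to 67918390, GRCh38) was at 1832 ± 123 normalized counts in the controls (SD, n = 2), 1299.7 ± 36.5 with sh1 (SD, n = 3) and 1165 ± 60.1 with sh3 (SD, n = 3). This is a fall by 29.1% with sh1 and by 36.4% with sh3, and a log2 fold change of -0.57 ± 0.063 (SE, limma adjusted p = 0.00030) for the mean of the constructs. The knockdown was therefore partial in both arms. The constructs differed in SIRT1 by 0.16 ± 0.063 on the log2 scale, with an adjusted p of 0.14, so that no difference in knockdown between them was established.

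**Figure D1:**
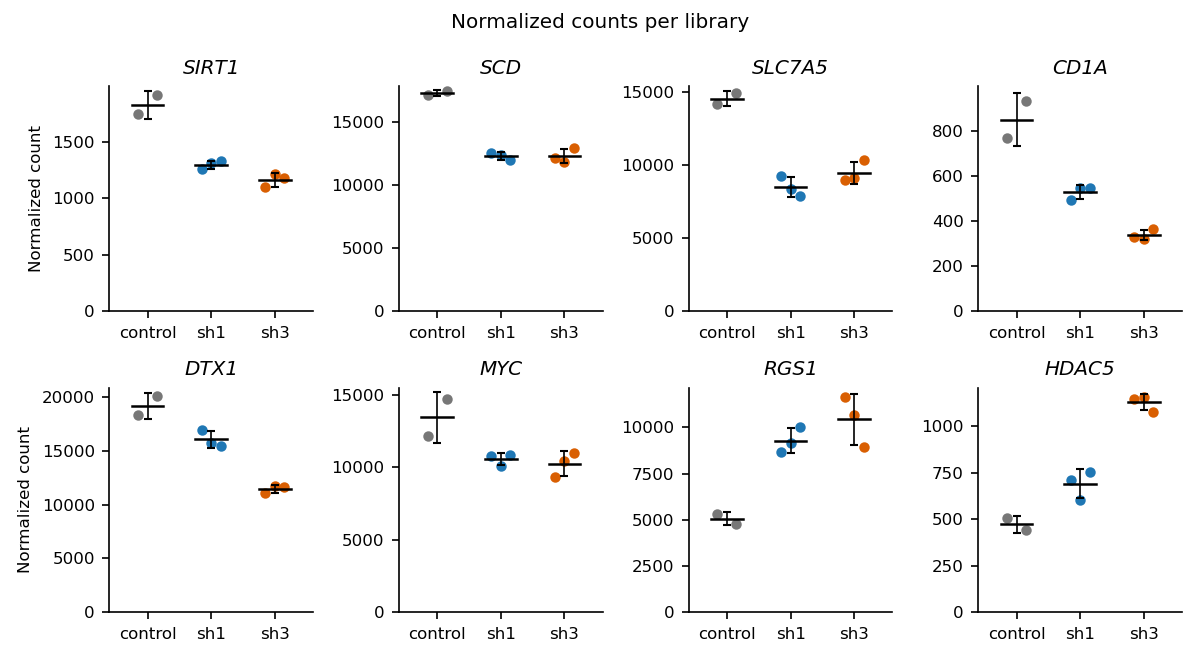
Normalized counts per library for SIRT1 and 7 other named genes. Each point is a library, horizontal bars are group means and whiskers are SDs (control n = 2, sh1 n = 3, sh3 n = 3), and every vertical axis starts at 0. SIRT1 lies between 1099 and 1329 in the 6 knockdown libraries and at 1745 and 1920 in the controls, while DTX1 and HDAC5 move further with sh3 than with sh1.

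The comparison of SIRT1 knockdown with control asks which genes respond to loss of SIRT1 in these leukemia cells, with both constructs weighted equally. EFEMP1, which encodes an extracellular matrix glycoprotein (chromosome 2, 55865967 to 55924139), went from 442 ± 51.1 normalized counts in the controls (SD, n = 2) to 8.83 ± 4.95 with sh1 and 7.55 ± 4.85 with sh3 (SD, n = 3 each), 53.7-fold lower by the fitted mean. FCGR2A, a low-affinity Fc gamma receptor, fell 10.3-fold from 265 ± 12.5 in the controls, and SHC4, an adaptor of receptor tyrosine kinases, fell 8.68-fold from 288 ± 2.61. All 3 were called with each construct, and the log2 differences between sh1 and sh3 of 0.18 ± 0.49, -0.018 ± 0.29 and -0.43 ± 0.20 (SE) had adjusted p of 0.86, 0.98 and 0.20. Among the 10 largest rises by the naming rule, the most abundant gene in the controls was RGS1, a regulator of G protein signalling in lymphocytes, which went from 5059 ± 360.0 to 9289 ± 686 with sh1 and 10432 ± 1368 with sh3, a 1.94-fold rise (adjusted p = 8.9e-05).

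In all, 1768 of the 13885 genes passed an adjusted p of 0.05 in limma, 909 of them higher and 859 lower in the knockdown. A change of at least 1 on the log2 scale was reached by 121 of them, of which 24 rose and 97 fell. The median size of the called changes was 0.30 on the log2 scale. In 1523 of the 1768 all 6 knockdown libraries lay beyond both controls in the same direction, as did 23.2% of all genes tested, while chance gives 7.14%. Other large falls that met this criterion were in CD1E (-2.63 ± 0.27 on the log2 scale, SE), a CD1 family member of cortical thymocytes, CD300A (-2.45 ± 0.25), an inhibitory receptor, and LSAMP (-2.16 ± 0.18), a cell adhesion molecule. CTSG (-2.10 ± 0.16), a serine protease of myeloid granules, and CD244 (-1.98 ± 0.15), a receptor of the SLAM family, fell as well. OR10R2, an olfactory receptor gene on chromosome 1 beyond the CD1 genes, changed by -3.54 ± 0.61, and NCKAP1, a subunit of the actin-regulating WAVE complex, by -2.41 ± 0.60. Among the rises, CD248, a transmembrane glycoprotein best known from stromal cells, went from 26.7 ± 7.41 to 81.2 ± 18.5 with sh1 and 114 ± 19.1 with sh3 (3.53-fold). EMP3, a tetraspan membrane protein, rose 2.10-fold, DUSP16, a phosphatase of stress-activated kinases, 2.08-fold, and ITGB3, the integrin beta 3 chain, 1.94-fold. NECTIN1 (1.53), DENND3 (1.26), RASA4B (1.12), DRC3 (0.997) and SOD1P3 (1.09), a pseudogene that can share reads with SOD1, completed the 10 largest rises among called genes with a mean of at least 50 and every knockdown library beyond both controls. Of the 1768 genes 522 also differed between the constructs. With sh1 alone CD300A (-0.21, adjusted p = 0.71), CD1E (-0.98, adjusted p = 0.080), OR10R2 (-1.32, adjusted p = 0.28), NECTIN1 (1.03, adjusted p = 0.067), DENND3 (0.87, adjusted p = 0.10) and DRC3 (0.97, adjusted p = 0.053) were not called.

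The count fell to 953 genes without control A and to 339 without control C, where the other control stands alone, of which 821 and 315 were among the 1768 with the same sign. Without control C the change of NCKAP1, which stood at 34.6 in control A and 276 in control C, was -0.93 (adjusted p = 0.34). There OR10R2 (-3.50, adjusted p = 0.066), NECTIN1 (0.93, adjusted p = 0.068), SOD1P3 (1.06, adjusted p = 0.076), RASA4B (1.37, adjusted p = 0.052) and DRC3 (1.28, adjusted p = 0.054) also missed the threshold. DENND3 (0.77, adjusted p = 0.096), RASA4B (0.86, adjusted p = 0.13) and DRC3 (0.71, adjusted p = 0.17) missed it without control A.

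Among the gene groups fixed before the data were examined, cholesterol and fatty acid synthesis was called downward. Of 28 measured genes of this group 20 fell and 0 rose (23 and 1 adjusted over the list alone), with a mean log2 change of -0.34 (camera adjusted p = 3.8e-15; adjusted p = 0.077 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell from 17358 ± 256 normalized counts in the controls (SD, n = 2) to 12323 ± 301 with sh1 and 12336 ± 549 with sh3 (SD, n = 3 each). Amino acid transport and synthesis genes under ATF4 also fell, 16 of 28 with 1 rise (18 and 3 adjusted over the list alone; mean -0.26, camera adjusted p = 3.7e-08; adjusted p = 0.13 with an estimated correlation). The constructs were unlike here, with 18 falls and 0 rises with sh1 (mean -0.35) and 10 falls and 4 rises with sh3 (mean -0.16). The large neutral amino acid transporter SLC7A5 went from 14534 ± 509 to 8499 ± 677 with sh1 and 9462 ± 748 with sh3. Its partner chain SLC3A2 went from 8679 ± 417 to 6350.3 ± 153 and 6358 ± 94.5, and the glutamine carrier SLC1A5 from 10174 ± 437 to 6608 ± 96.2 and 7729 ± 434.

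Genes of T-cell receptor signalling and thymocyte identity fell in 15 of 27 cases and rose in 4 (17 and 4 adjusted over the list alone), with a mean of -0.51 (camera adjusted p = 4.7e-07; adjusted p = 0.056 with an estimated correlation). CD1A, a marker of cortical thymocytes, went from 849 ± 116 to 528 ± 31.3 with sh1 and 337 ± 23.9 with sh3, and CD7, a pan-T surface protein, from 12766 ± 753 to 9848 ± 244 and 7074 ± 517. CD1B fell over the mean of the constructs (-0.59 ± 0.051, SE) and did so with sh3 (-1.14, adjusted p = 9.8e-07), while its change with sh1 was -0.042 (adjusted p = 0.72). DNTT, the template-independent DNA polymerase of V(D)J joining (-2.68 ± 0.40), TCF7, a transcription factor of early T cells (-1.47 ± 0.22), and CD2 (-1.42 ± 0.26) fell furthest beside CD1E, and these 3 were chosen after their values were seen. DNTT was not taken by the naming rule although its fall exceeds that of CD1E. That rule requires a mean of at least 50 and every knockdown library beyond both controls. The risers of the group were RAG1, GATA3, BCL11B and ARPP21, named because they went against its mean, and GATA3 went from 2915 ± 48.3 to 3133 ± 51.9 and 4324 ± 255. RAG1 missed the threshold without control C (0.20, adjusted p = 0.084). With sh1 none of the 4 was called, their values being RAG1 (0.15, adjusted p = 0.070), GATA3 (0.10, adjusted p = 0.32), BCL11B (0.11, adjusted p = 0.49) and ARPP21 (0.18, adjusted p = 0.13). DNTT (-1.08, adjusted p = 0.18) and TCF7 (-0.83, adjusted p = 0.069) were not called with sh1 either.

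NOTCH1 targets split, with 7 of 23 lower and 2 higher (10 and 2 adjusted over the list alone), a mean of -0.15 and a camera adjusted p of 0.012 (adjusted p = 0.13 with an estimated correlation). With sh1 alone this list was not called (mean -0.0030, camera adjusted p = 0.46, fry adjusted p = 0.099). DTX1, a NOTCH1-induced ubiquitin ligase, fell from 19136 ± 1245 to 16047 ± 786 with sh1 and 11468 ± 364 with sh3, and NOTCH3 changed by -0.45 ± 0.051 on the log2 scale (SE, adjusted p = 0.00035). HES1, the classical NOTCH target, rose by 0.33 ± 0.072 (adjusted p = 0.014) and the cyclin gene CCND3 by 0.33 ± 0.037 (adjusted p = 0.00036). The call of HES1 ended without control A (0.26, adjusted p = 0.12) and without control C (0.39, adjusted p = 0.065). NOTCH1 itself was at 10517 ± 331 in the controls and changed by -0.20 ± 0.075 (adjusted p = 0.11). Without sh1 A that change was -0.24 with an adjusted p of 0.021. MYC, the growth-promoting transcription factor, went from 13433 ± 1765 to 10542 ± 408 and 10252 ± 846 (adjusted p = 0.0093), a call that ended without control C (-0.23, adjusted p = 0.16). MYC target genes fell in 6 of 32 cases and rose in 1 (7 and 1 adjusted over the list alone; mean -0.11, camera adjusted p = 2.0e-05; adjusted p = 0.40 with an estimated correlation). They include the transferrin receptor gene TFRC (-0.37) and the nucleolar genes NOLC1 (-0.20) and NOP56 (-0.19). The rise, chosen after its value was seen, was in NME1 (0.23). NOLC1 and NOP56 missed the threshold without control C (-0.14, adjusted p = 0.19, and -0.14, adjusted p = 0.19). Not called with sh1 were NOTCH3 (-0.15, adjusted p = 0.14), HES1 (0.12, adjusted p = 0.44), NOLC1 (-0.052, adjusted p = 0.57), NOP56 (-0.12, adjusted p = 0.15) and NME1 (0.23, adjusted p = 0.069).

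Cell cycle genes were slightly higher. Of 32 mitotic genes 13 rose and 0 fell (18 and 0 adjusted over the list alone; mean 0.14, camera adjusted p = 4.2e-08; adjusted p = 0.13 with an estimated correlation). Examples are the spindle checkpoint kinase TTK (3983 ± 257 in the controls, 4977 ± 115 with sh1, 5200.5 ± 53.7 with sh3) and the kinetochore gene NDC80 (0.31 ± 0.045). Of 32 DNA replication genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; mean 0.071, camera adjusted p = 0.0046; adjusted p = 0.29 with an estimated correlation), led by E2F8 (0.48 ± 0.060). Ribosomal protein genes fell in 9 of 36 cases with 0 rises (21 and 0 adjusted over the list alone; mean -0.17, camera adjusted p = 4.8e-09; adjusted p = 0.47 with an estimated correlation; fry adjusted p = 0.14). An example is RPL6 (-0.34 ± 0.062), whose call ended without control C (-0.27, adjusted p = 0.11).

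Antioxidant genes under NRF2 fell in 6 of 19 cases with 0 rises (10 and 0 adjusted over the list alone; mean -0.19, camera adjusted p = 4.6e-06; adjusted p = 0.13 with an estimated correlation). The cystine transporter SLC7A11, also a member of the ATF4 group, went from 1092 ± 18.2 to 633 ± 23.2 and 581 ± 115, and the ferritin heavy chain gene FTH1 from 13895 ± 1270.4 to 10872 ± 1073 and 9117 ± 273. Lysosome and autophagy genes fell in 8 of 30 cases and rose in 2 (11 and 3 adjusted over the list alone; mean -0.080, camera adjusted p = 0.0065; adjusted p = 0.13 with an estimated correlation), including the lysosomal protease gene CTSD (-0.48 ± 0.047) and LAMP1 (-0.28 ± 0.042). Hypoxia-regulated genes rose in 5 of 23 cases with 0 falls (6 and 0 adjusted over the list alone; mean 0.21, camera adjusted p = 0.0082; adjusted p = 0.41 with an estimated correlation; fry adjusted p = 0.11). Among them were the histone demethylase gene KDM3A (0.41 ± 0.063) and the mTORC1 inhibitor DDIT4 (0.46 ± 0.10), and both missed the threshold without control C (0.29, adjusted p = 0.057, and 0.27, adjusted p = 0.23). ANKZF1 (0.31) rose too, as did EGLN1 (0.34) and ADM (1.31), which were chosen after their values were seen. The call of ANKZF1 ended without control A or control C (0.34, adjusted p = 0.053, and 0.29, adjusted p = 0.13). The changes of DDIT4 (0.13, adjusted p = 0.57), ANKZF1 (0.18, adjusted p = 0.17), EGLN1 (0.32, adjusted p = 0.066) and ADM (0.90, adjusted p = 0.17) were not called with sh1. The hypoxia list itself, with 1 rise and 1 fall, was not called with sh1 either (camera adjusted p = 0.12, fry adjusted p = 0.33). The group of histone acetylation enzymes, which mixes acetyltransferases with deacetylases, held 4 rises and 0 falls in 30 genes (4 and 0 adjusted over the list alone; mean 0.10, camera adjusted p = 0.0046; adjusted p = 0.13 with an estimated correlation). Its risers were the class II deacetylases HDAC5 (474 ± 45.8 in the controls, 689 ± 78.4 with sh1, 1126 ± 43.0 with sh3) and HDAC7 (0.60 ± 0.085) and the acetyltransferases KAT6A (0.26 ± 0.060) and KAT7 (0.17 ± 0.046, adjusted p = 0.034). KAT7 missed the threshold without sh1 B, sh3 A, sh3 B, control A or control C, with log2 changes of 0.14 to 0.20 and adjusted p between 0.064 and 0.19, and KAT6A without control C (0.19, adjusted p = 0.22). HDAC7 was called with sh3 (adjusted p = 3.3e-05) and not with sh1 (0.10, adjusted p = 0.57). Nor was KAT6A called with sh1 (0.19, adjusted p = 0.12), and KAT7 was not with sh3 (0.11, adjusted p = 0.18). With sh1 the group of histone acetylation enzymes was not called by camera (adjusted p = 0.054), while fry called it (adjusted p = 0.012).

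**Figure D2:**
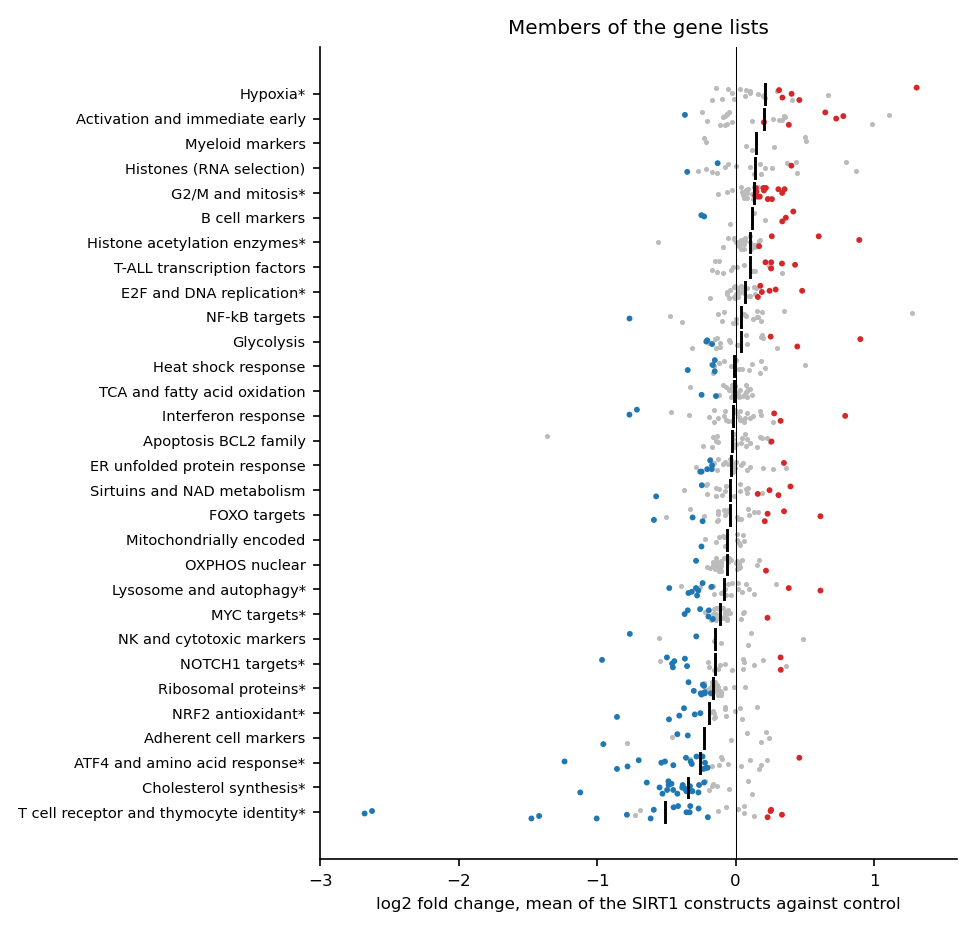
Log2 fold change of each measured member of 30 gene lists, for the mean of the SIRT1 constructs against control. Each point is a gene (red, rose; blue, fell; grey, adjusted p not under 0.05), the black bar is the mean of the list, and an asterisk marks the 12 lists called by camera at its preset correlation. The cholesterol synthesis list holds 20 genes that fell and 0 that rose.

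Of the 31 lists tested, 12 passed camera with a preset correlation of 0.01, 4 of them upward and 8 downward. With a correlation estimated from the data 0 of the 31 passed and 13 had an unadjusted preset-correlation p under 0.05, while fry, which tests whether a list moves on balance in a single direction, called 14. These include 4 that camera did not call, namely early activation genes (fry adjusted p = 0.016) and T-ALL transcription factors (0.020) upward, and the ER unfolded protein response (0.0084) and NK and cytotoxic markers (0.021) downward.

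The construct sh1 was compared with control alone to see what that hairpin changed. The largest rise by the naming rule was in APP, the amyloid precursor protein gene (chromosome 21, 25880550 to 26171128), which went from 107 ± 4.81 normalized counts in the controls (SD, n = 2) to 795 ± 56.0 with sh1 (SD, n = 3) and stood at 49.0 ± 17.4 with sh3. KLHL4, a kelch-like gene of the X chromosome, fell from 2822 ± 5.63 to 657 ± 26.1 with sh1 (log2 change -2.10 ± 0.063, SE, adjusted p = 1.4e-08) and was at 2583 ± 107 with sh3. SLC18B1, a vesicular polyamine transporter, rose from 25.6 ± 5.97 to 116 ± 11.6, CASKIN1 from 28.1 ± 11.8 to 110.0 ± 9.99, CD248 from 26.7 ± 7.41 to 81.2 ± 18.5 and CABLES1 from 72.7 ± 5.90 to 188 ± 60.9. By the same rule the largest falls beside KLHL4 were in EFEMP1 (-5.66), FCGR2A (-3.37), SHC4 (-3.33) and NCKAP1 (-2.50).

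With sh1, 876 genes passed limma at an adjusted p of 0.05, 400 higher and 476 lower. Camera called 10 of 31 lists and 0 with an estimated correlation. Fry called 10, without the MYC target and ribosomal protein lists and with the histone acetylation enzyme and NK lists. The ATF4 group stood out, with 18 of 28 lower and 0 higher (19 and 1 adjusted over the list alone; mean -0.35, camera adjusted p = 1.3e-15; adjusted p = 0.055 with an estimated correlation). Cholesterol synthesis genes followed, with 13 of 28 lower and 0 higher (20 and 0 adjusted over the list alone; mean -0.30, camera adjusted p = 5.0e-15; adjusted p = 0.055 with an estimated correlation). The ER unfolded protein response list had 6 of 28 genes lower and 1 higher (9 and 1 adjusted over the list alone; mean -0.12, camera adjusted p = 0.00011; adjusted p = 0.055 with an estimated correlation). The T cell, NRF2, ribosomal protein, MYC target and lysosome lists were called downward and the mitotic and DNA replication lists upward, with adjusted p between 0.061 and 0.55 with an estimated correlation. The count was 377 without sh1 B, 351 without control A and 159 without control C. NCKAP1 lost its call without any of sh1 A to C, sh3 A to C or control C (adjusted p up to 0.37, with a log2 change of -1.02 without control C), CABLES1 without control A or control C (1.23 and 1.39, adjusted p = 0.096 and 0.091) and CD248 without control C (1.297, adjusted p = 0.071).

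The construct sh3 was likewise compared with control alone. CD300A fell from 423 ± 1.93 normalized counts in the controls (SD, n = 2) to 16.5 ± 6.80 with sh3 (SD, n = 3), and CD1E from 4533 ± 163 to 257 ± 142, with log2 changes of -4.68 ± 0.28 and -4.27 ± 0.30 (SE). EFEMP1 (-5.84), OR10R2 (-5.77) and FCGR2A (-3.35) were the other members of the 5 largest falls by the naming rule. NOG, a secreted antagonist of bone morphogenetic proteins, rose from 38.4 ± 3.43 to 143 ± 20.7, NECTIN1 from 61.8 ± 34.8 to 236 ± 33.4, DENND3 from 25.04 ± 11.98 to 76.8 ± 10.1 and CD248 from 26.7 ± 7.41 to 114 ± 19.1. UTP14C, a copy of UTP14A that can share its reads, was listed at 0 in both controls and at 339, 265 and 10.6 in sh3 A, B and C, and its call ended without sh3 A, sh3 B or either control, with adjusted p between 0.11 and 0.16.

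With sh3, 2576 genes passed limma at an adjusted p of 0.05, 1300 higher and 1276 lower. Camera called 16 of 31 lists, 1 of them with an estimated correlation. Fry called 14, without the ribosomal protein (adjusted p = 0.15) and mitochondrially encoded (adjusted p = 0.13) lists. The list that kept its call was that of T-cell receptor and thymocyte identity, with 16 of 27 genes lower and 4 higher (18 and 4 adjusted over the list alone; mean -0.74, camera adjusted p = 5.2e-07; adjusted p = 0.049 with an estimated correlation). Cholesterol synthesis had 21 of 28 lower and 1 higher (24 and 1 adjusted over the list alone; mean -0.38, camera adjusted p = 2.3e-12; adjusted p = 0.11 with an estimated correlation). NOTCH1 targets had 12 of 23 lower and 3 higher (12 and 4 adjusted over the list alone; mean -0.30, camera adjusted p = 0.0015; adjusted p = 0.11 with an estimated correlation). The list of B cell markers, some of which DND41 expresses at high level, had 4 of 8 higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0068; adjusted p = 0.37 with an estimated correlation). The smallest p was that of EBF1 (899.5 ± 3.17 in the controls, 1461 ± 78.1 with sh3). The ATF4, MYC target, ribosomal protein, NRF2, lysosome and mitochondrially encoded lists were also called downward and the mitotic, DNA replication, hypoxia, histone acetylation enzyme, T-ALL transcription factor and early activation lists upward, with adjusted p between 0.13 and 0.53 with an estimated correlation. TLX3, the homeobox oncogene of a T-ALL subtype, was at 7463 ± 49.6 in the controls and 12829 ± 628 with sh3 (adjusted p = 3.3e-06). Without the library sh3 C, whose labels conflict, 2233 genes passed. The count was 1537 without sh3 A, 1563 without sh3 B and 860 without control C.

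Genes called with both constructs in the same direction numbered 536, of which 260 rose and 276 fell, and 22 were called in opposite directions. They include SIRT1, EFEMP1, FCGR2A, SHC4, SLC7A5, IFI6, JUN and RGS1. IFI6, an interferon-induced gene, went from 2543 ± 160.2 in the controls to 1645 ± 127 and 1464 ± 29.6, and JUN, a subunit of the AP-1 transcription factor, from 1649.8 ± 12.03 to 2652 ± 208 and 2540.3 ± 316. Because both comparisons use the same 2 controls, chance alone links them. In 100 simulations all 8 libraries, controls included, were redrawn as unchanged, with noise independent between genes. A mean of 0.06 genes (highest 2) was then called in both. With no gene changed, few calls can arise with either construct, so that this mean is not a chance level for the 536. Separate effects of sh1 and sh3 against shared controls were not simulated. Since the simulations hold no joint shift of genes in the controls, they cannot show how many shared calls such a shift would give. Independent lists of the observed sizes would share 81.2 (37.5 higher, 43.7 lower). Across genes, which are not independent replicates, the effects of sh1 and sh3 correlated at 0.556, against 0.597 on average in the simulations, while their covariance was 0.0799 against a simulated 0.0313, a difference of 0.0486. The 2 controls cannot be split with 2 in each part, so that part of the excess in shared calls may come from them. The count of shared calls was 235 without sh1 B, 328 without sh3 A, 329 without sh3 B, 239 without control A and 82 without control C.

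The constructs were compared directly to see where their effects differ. CYSLTR2, a cysteinyl leukotriene receptor, was at 902 ± 74.8 normalized counts in the controls (SD, n = 2), 1444 ± 56.0 with sh1 and 106 ± 35.6 with sh3 (SD, n = 3 each). CD300A was at 365 ± 12.1 with sh1 and 16.5 ± 6.80 with sh3. ANKS6, an ankyrin repeat protein of primary cilia, was at 134 ± 24.7 with sh1 and 9.10 ± 6.31 with sh3, and OR10R2 at 77.6 ± 5.11 and 4.04 ± 3.98. Lower with sh1 than with sh3 were KLHL4, the SLAM family receptor LY9 (33.01 ± 0.473 against 127 ± 15.6), the G protein regulator RGS16 (213 ± 12.1 against 649 ± 29.4), the tumor necrosis factor receptor gene TNFRSF1B (198 ± 49.98 against 594 ± 77.4) and NOG. APP, LY9 and RGS16 were called against control in opposite directions, with LY9 at 81.0 ± 10.9 and RGS16 at 447 ± 13.3 in the controls.

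The difference passed limma at an adjusted p of 0.05 for 1589 genes, 779 higher and 810 lower with sh1 than with sh3. Of these, 837 were called against control with sh3 and not with sh1, 166 with sh1 and not with sh3, and 478 with neither. Camera called 7 of 31 lists for the difference and 0 with an estimated correlation. Fry called 9, without the mitochondrially encoded list and with the histone acetylation enzyme, T-ALL transcription factor and early activation lists. The T cell list was higher with sh1 (11 of 27 genes higher and 4 lower, 14 and 6 adjusted over the list alone, camera adjusted p = 0.0012; adjusted p = 0.13 with an estimated correlation). NOTCH1 targets were higher as well (9 of 23 higher and 4 lower, 10 and 6 adjusted over the list alone, camera adjusted p = 0.021; adjusted p = 0.14 with an estimated correlation). The ATF4 list was lower with sh1 (14 of 28 lower and 0 higher, 17 and 0 adjusted over the list alone, camera adjusted p = 7.7e-08; adjusted p = 0.14 with an estimated correlation). The ER unfolded protein response list was also lower (11 of 28 lower and 0 higher, 14 and 1 adjusted over the list alone, camera adjusted p = 2.5e-05; adjusted p = 0.098 with an estimated correlation). The B cell list was lower too (5 of 8 lower and 0 higher, 7 and 0 adjusted over the list alone, camera adjusted p = 1.9e-06; adjusted p = 0.15 with an estimated correlation). The count of differing genes was 1236 without sh3 C, 1019 without sh1 B, 965 without sh3 A and 925 without sh3 B.

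**Figure D3:**
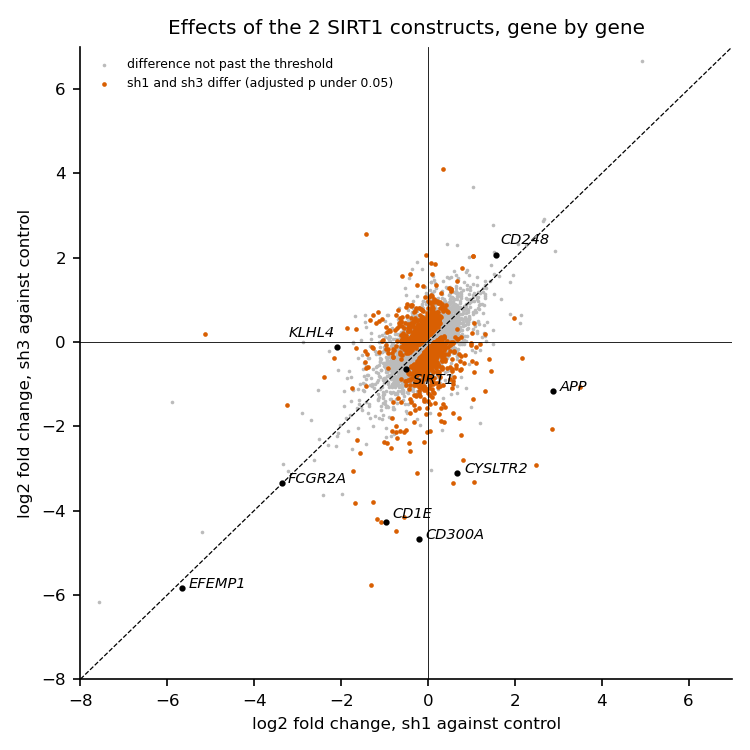
Log2 fold change against control with sh1 (horizontal axis) and with sh3 (vertical axis) for the 13885 genes tested. Each point is a gene, orange where the difference between the constructs has an adjusted p under 0.05 (1589 genes), black for the genes named in the plot, and the dashed line marks equal effects. EFEMP1 and FCGR2A lie close to that line, while APP, CD300A and KLHL4 lie far from it. Both axes share the same controls, which adds to the spread along the line.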

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

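The test of whether sh3 acts as a larger dose and the removal of the length and GC trend were chosen only after the results were seen. The effects of the 2 constructs under the same contrast with control differed for 1589 genes by limma's test of the difference. Under a larger dose with sh3 few of these genes should have a larger called effect with sh1, yet 199 of them, 12.5%, did so, which argues against dose as the whole cause, while 1142 of them had the larger effect with sh3, as a dose difference would give for a part. Off-target binding through the hairpins' seeds stays open, since the heptamer TTCCTTT, found in SIRT1 messenger RNA as are 20.4% of all heptamers tested, marked genes lower with sh3 than with sh1 (adjusted p = 0.0229 by Bonferroni) and was carried by 44.0% of the 741 differing genes that were lower with sh3 than with sh1, 36.3% of the 783 lower with sh1 than with sh3 and 33.4% of all. Its carriers differed by 0.038 on the log2 scale after adjustment for the length and GC content of the untranslated region and the mean level. Without that adjustment they differed by 0.00997, and the carrier shares above are likewise unadjusted. Against control the adjusted difference of carriers from other genes was -0.025 with sh3 and 0.013 with sh1. The heptamer ranked 83 of 15935 in sh3 against control, where the leading heptamer of lower genes had a Bonferroni p of 0.33. The hairpin sequences are not given in the sources used here, so that the part of the difference due to off-target binding cannot be told. A biological difference between the constructs was not tested. The split of the 6 knockdown libraries by construct was 1 of 10 splits, with 1589 genes against at most 1 in the others, and 10 splits are too few for a share under 0.05.

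The gene lists whose effects differed between the constructs, as mean log2 difference of sh1 minus sh3, were T cell receptor and thymocyte identity (0.46), NOTCH1 targets (0.29) and mitochondrially encoded genes (0.086) on the higher side. On the lower side were B cell markers (-0.37), the ATF4 and amino acid response (-0.20), the ER unfolded protein response (-0.16) and the interferon response (-0.11). With an estimated correlation none of these 7 passed, with adjusted p of 0.098 to 0.62.

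Named genes that differed in the same test are given by the log2 difference of sh1 minus sh3. The largest positive values among them were CD300A 4.47, OR10R2 4.45, APP 4.04, ANKS6 3.92, CYSLTR2 3.80, CD1E 3.30 and SLC18B1 2.55. Also on that side were CD1B 1.097, CD1A 0.65, CD7 0.48, CD244 0.69, NOTCH3 0.60, DTX1 0.48, NOTCH1 0.28, LTB 0.52, BST2 0.97, CTSG 1.06 and FN1 1.33. CASKIN1 1.42, CABLES1 1.12, CYCS 0.45, NOLC1 0.29, TFRC 0.24, FTH1 0.25, H3F3B 0.26 and MT-ND1 0.20 were also higher with sh1 than with sh3.

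The largest negative values among them were KLHL4 -1.97, LY9 -1.91, NOG -1.79, RGS16 -1.60, TNFRSF1B -1.60, NECTIN1 -0.999 and HDAC7 -0.998. Also lower with sh1 than with sh3 were HES1 -0.42, TLX3 -0.70, GATA3 -0.46, SOX4 -0.20, EBF1 -0.56, POU2AF1 -0.38, CD79A -0.37, IGLL1 -0.40, RAG1 -0.15, CCND3 -0.23 and CDKN1B -0.19. Others on that side were SLC2A3 -0.73, DDIT4 -0.67, IER2 -0.48, CMPK2 -0.45, PFKFB3 -0.31, ANKZF1 -0.26, SLC1A5 -0.22, SEC24D -0.22, LAMP1 -0.18, PDGFRB -0.23 and HDAC5 -0.71.

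Changes of whole gene lists in the knockdown could reflect a trend with transcript length or GC content, which the log2 changes follow weakly (Spearman coefficients of 0.137 and -0.183 across 13800 genes, 1.398% of the variance). After removal of that trend within each library the mean change of the cholesterol synthesis list was -0.34 (-0.34 before), that of the ATF4 list -0.24 (-0.26 before), that of the mitotic list 0.12 (0.14 before) and that of the ribosomal protein list -0.13 (-0.17 before), each still called by camera at the preset correlation. The trend is thus argued against as the whole cause of the 4 changes. What stays open is that members of a list vary together, since the estimated correlation between ribosomal protein genes was 0.850 and that between cholesterol genes 0.105, so that 2 controls leave a joint shift of a list by culture conditions, untested here, as a candidate source of these changes.

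The large falls shared by both constructs include FCGR2A and CTSG, which are best known from myeloid cells, so that a few such cells in the control cultures could account for them. The most abundant of the myeloid genes LYZ, S100A8 and S100A9 had a control mean of 19.9 normalized counts (S100A9), against 265 for FCGR2A, and stood at 20.95 with sh1 and 23.3 with sh3, which argues against that source. An effect of the hairpin vector common to both SIRT1 constructs was not tested. Nor can these 8 libraries tell a fall with the SIRT1 hairpins from a higher level of these genes in the 2 control cultures. With technical sources left open, loss of SIRT1 remains a hypothesis for these falls.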

How the results depend on the processing

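The removal of the length and GC trend and the fit on letters A and C were chosen after seeing the data. Of 2832 values of 136 gene results under the alternatives, 2623 stayed on their side of the threshold in the same direction, 207 lost a call, 2 gained a call and 0 reversed. Of 710 values of 31 lists, 682 stayed, 14 lost a call, 14 gained a call and 0 reversed. These pooled counts include settings that could change little. Median of ratios scaling left the deposited values almost as they were and lost 0 gene calls, as did a pseudocount of 0.5. The pooled share that stayed is therefore not a measure of stability. SIRT1 passed the threshold in each alternative, with a log2 change of -0.64 to -0.50 when a library was left out. Most losses came without control C (55 gene results), with a variance prior without a trend (36) and without control A (22), and a lone control is assumed to vary like the other groups. The filter at a mean of 100 gave values for 112 of the 136. The median log2 change of all genes stayed within 0.0055 of 0 in each setting. Depth may limit genes near the filter, where a value rests on few steps, and this was not tested. Fits on fewer libraries have fewer samples, and for the other settings the cause was not tested.

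The knockdown count of 1768 was 744 without the variance trend, 862 with letters A and C, 394 with 2 groups of 6 and 2 libraries and 339 to 1898 when a library was left out. For sh1, 876 became 236, 266, 462 with the 5 libraries compared and 159 to 782. For sh3, 2576 became 1531, 1273 and 860 to 2931 in the order of trend, letters and left-out library. In that order the 536 genes called with both constructs became 137, 134 and 82 to 465, and the 1589 differing genes 968, 562 and 925 to 1770. Other settings stayed within 1.5 times these counts, apart from the replicate block below.

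The letters do not pair the libraries, since deviations from the group means correlated at -0.062 to 0.058 in 7 pairs with the same letter. With a replicate block 1292 genes were called for the knockdown (1210 of them among the 1768 with the same sign), 549 for sh1, 2071 for sh3, 341 for both constructs and 1495 for the difference, and 12 of the 136 gene results lost their call.

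Between 12 and 14 lists were called when a library was left out, and fry called 14, without the hypoxia and ribosomal protein lists. Camera with an estimated correlation called 0. For the T cell, NOTCH1 target, lysosome and histone acetylation enzyme lists the estimated correlations were -0.018, -0.0089, -0.0099 and -0.013. These lie below the preset 0.01, so that a higher correlation does not account for the loss of these calls. With an estimated correlation camera tests on the 5 residual degrees of freedom of the model, which gives a larger p-value for the same statistic. How much of the loss this makes up in lists with a higher estimated correlation was not tested.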

Other observations

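Several groups that camera did not call as lists in the knockdown held single genes that changed. Among them fry called the ER unfolded protein response and NK and cytotoxic markers downward, both described below. It called early activation genes and T-ALL transcription factors upward. Camera with an estimated correlation gave the 2 lists called upward adjusted p of 0.40 and 0.41. With sh1 alone fry called neither of these 2 (adjusted p = 0.26 and 0.33). FOXO targets held 4 rises and 3 falls in 25 genes (4 and 5 adjusted over the list alone; camera adjusted p = 0.60, fry 0.58). Among them was the cell cycle inhibitor CDKN1B (0.35 ± 0.046 on the log2 scale, SE). Early activation genes held 5 rises and 1 fall in 26 genes (6 and 1 adjusted over the list alone; camera adjusted p = 0.12, fry 0.016), with JUN at 0.65 ± 0.083 and IER2 at 0.39 ± 0.060. T-ALL transcription factors held 5 rises and 0 falls in 19 genes (6 and 1 adjusted over the list alone; camera adjusted p = 0.058, fry 0.020), with TLX3 at 0.43 ± 0.044 and SOX4 at 0.22 ± 0.046. Interferon response genes held 3 rises and 2 falls in 31 genes (3 and 2 adjusted over the list alone; camera adjusted p = 0.98, fry 0.81), with BST2 at -0.77 ± 0.085 and CMPK2 at 0.33 ± 0.053. NF-kB targets held 0 rises and 1 fall in 19 genes (0 and 1 adjusted over the list alone; camera adjusted p = 0.75, fry 0.58), and the fall was in LTB, which encodes lymphotoxin beta (-0.77 ± 0.093). Sirtuins and NAD enzymes held 4 rises and 2 falls in 23 genes (5 and 7 adjusted over the list alone; camera adjusted p = 0.57, fry 0.14). Beside SIRT1 they included the poly(ADP-ribose) polymerase PARP2 (0.40 ± 0.056) and NAMPT (0.25 ± 0.049), and CD38, chosen after its value was seen, was the other fall. Without control C the log2 changes that missed the threshold include those of IER2 (0.34, adjusted p = 0.055), SOX4 (0.19, adjusted p = 0.14) and NAMPT (0.19, adjusted p = 0.14). With sh1 the genes not called include TLX3 (0.080, adjusted p = 0.37), SOX4 (0.12, adjusted p = 0.20), IER2 (0.14, adjusted p = 0.23), BST2 (-0.28, adjusted p = 0.11) and CMPK2 (0.10, adjusted p = 0.34), and with sh3 CD38 (-0.10, adjusted p = 0.27).

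Among genes of energy metabolism, the glucose transporter SLC2A3 moved most of those named here, from 1278 ± 137 normalized counts (SD, n = 2) to 1862 ± 240.3 with sh1 and 3077 ± 373 with sh3 (SD, n = 3 each). Glycolysis genes held 3 rises and 3 falls in 23 genes (5 and 8 adjusted over the list alone; camera adjusted p = 0.86, fry 0.73). Nuclear genes of oxidative phosphorylation held 1 rise and 1 fall in 32 genes (1 and 1 adjusted over the list alone; camera adjusted p = 0.11, fry 0.58), SDHA (0.22) and CYCS (-0.28). Mitochondrially encoded genes held 0 rises and 1 fall in 13 genes (0 and 1 adjusted over the list alone; camera adjusted p = 0.12, fry 0.38), with MT-ND1 at -0.25. The TCA cycle with fatty acid oxidation held 0 rises and 2 falls in 29 genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.98, fry 0.83), ACADVL (-0.14) and SLC25A20 (-0.24). Heat shock genes held 0 rises and 4 falls in 19 genes (1 and 7 adjusted over the list alone; camera adjusted p = 0.27, fry 0.52), and the ER unfolded protein response 1 rise and 6 falls in 28 genes (4 and 8 adjusted over the list alone; camera adjusted p = 0.14, fry 0.0084). The BCL2 family held 1 rise and 0 falls in 25 genes (1 and 0 adjusted over the list alone; camera adjusted p = 0.57, fry 0.17). Histones held 1 rise and 2 falls in 21 genes (3 and 2 adjusted over the list alone; camera adjusted p = 0.57, fry 0.52). Mean, median and test did not share a direction for glycolysis, NF-kB targets, the interferon response, the TCA cycle and the BCL2 family. Without control C the log2 changes that missed the threshold include those of SDHA (0.17, adjusted p = 0.14), CYCS (-0.21, adjusted p = 0.17), ACADVL (-0.14, adjusted p = 0.19) and SLC25A20 (-0.23, adjusted p = 0.27). Without control A the log2 changes that missed the threshold include those of MT-ND1 (-0.21, adjusted p = 0.071), ACADVL (-0.14, adjusted p = 0.13) and SLC25A20 (-0.26, adjusted p = 0.15). ACADVL also missed the threshold without sh1 B, sh3 A or sh3 C, and SLC25A20 without any other library except sh3 C. Among these genes CYCS, MT-ND1 and SLC25A20 were not called with sh1 (adjusted p = 0.64, 0.12 and 0.075), nor ACADVL and SLC25A20 with sh3 (adjusted p = 0.20 and 0.091). The ER unfolded protein response was called downward by fry, while camera with an estimated correlation gave an adjusted p of 0.33. Its mean was -0.12 with sh1 (fry adjusted p = 0.0012) and 0.046 with sh3 (fry adjusted p = 0.33), so that sh1 carried the fall.

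Markers of other cell types were not called by camera as lists in the knockdown, though fry called NK and cytotoxic markers downward. For that list camera with an estimated correlation gave an adjusted p of 0.59. Myeloid markers held 0 rises and 0 falls in 7 genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.96, fry 0.83), and the most abundant was AIF1 with 410.0 ± 25.7 normalized counts in the controls (SD, n = 2). NK and cytotoxic markers held 0 rises and 2 falls in 8 genes (0 and 2 adjusted over the list alone; camera adjusted p = 0.43, fry 0.021), EOMES (-0.76 ± 0.16, SE) and PRF1 (-0.28 ± 0.068). Adherent cell markers held 0 rises and 3 falls in 10 genes (0 and 3 adjusted over the list alone; camera adjusted p = 0.11, fry 0.059), FN1 (-0.95 ± 0.15), PDGFRB (-0.34 ± 0.067) and PECAM1 (-0.42 ± 0.10). B cell markers held 3 rises and 2 falls in 8 genes (4 and 2 adjusted over the list alone; camera adjusted p = 0.16, fry 0.14). CD79A was at 24848 ± 1215 in the controls, 18393 ± 841 with sh1 and 23843 ± 799.5 with sh3 (SD). Without control C the log2 changes that missed the threshold include those of EOMES (-0.84, adjusted p = 0.081), PRF1 (-0.26, adjusted p = 0.17), PECAM1 (-0.40, adjusted p = 0.17), PDGFRB (-0.31, adjusted p = 0.11) and CD79A (-0.20, adjusted p = 0.12). Without control A the log2 changes that missed the threshold include those of EOMES (-0.68, adjusted p = 0.092), PRF1 (-0.30, adjusted p = 0.081) and PECAM1 (-0.44, adjusted p = 0.099). Not called with sh1 were PRF1 (-0.18, adjusted p = 0.19) and FN1 (-0.29, adjusted p = 0.34), and not with sh3 PDGFRB (-0.23, adjusted p = 0.053), PECAM1 (-0.34, adjusted p = 0.065) and CD79A (-0.059, adjusted p = 0.48). Erythroid and megakaryocyte markers had 4 members above the filter and were not tested as a list.

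CD1A, CD1B, CD1E and OR10R2 start at 158254137, 158327951, 158353696 and 158472220 on chromosome 1, and each was called lower with sh3. LY9 ends at 160828261 on the same chromosome and its neighbour CD244 starts at 160830160. With sh3 LY9 was called higher (0.65 ± 0.19, SE, adjusted p = 0.039) and CD244 lower (-2.32 ± 0.16, adjusted p = 7.2e-06). With sh1 both were called lower (-1.26 ± 0.19 and -1.64 ± 0.16).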
